A study of Homo sapiens with 3 samples.

How the data were processed

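The data are single-cell expression profiles of the human breast cancer line MCF7, from 1 library of strain L and 2 libraries of clone 9. Per the labels' protocols, cells were grown in medium with 10% serum, dissociated, and made into libraries on a droplet platform that captures the 3' ends of transcripts. The unit is the UMI count: the deposited table holds whole-number counts per gene and cell, not normalized, for 20081 genes and 12092 cells of the 3 libraries. The submitters' processing notes name Cell Ranger 2.1.0 and the build GRCh38. How the authors chose the cells and which annotation they counted on is not given in the sources used here. Every gene of the table had a UMI in at least 3 cells. Each cell's name carries its library, and 0 columns were left out as unmapped.

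Because 3' ends are counted, a UMI stands for a transcript of a gene, and genes with near-identical copies share reads in ways the table does not show. Symbols were matched to GENCODE 29 for positions: 15936 genes matched by their symbol and 447 by an older symbol, 47 had more than 1 place and 3651 were not matched. Arms were set by position against approximate centromere positions on GRCh38, and 0 protein-coding genes spanned such a position.

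Cells were kept with at least 1000 genes and under 20% mitochondrial UMIs. This kept 3479 of 3681 cells (94.5%) of strain L, 4144 of 4295 (96.5%) of the May library and 4023 of 4116 (97.7%) of the Nov library. Scrublet as run in scanpy called almost no doublets, which is under 0.5% of cells, so its calls were not relied on. Doublets may remain among the cells, and whether the submitters had removed any is not known. Leaving out the 5% of cells with most UMIs per library was added as an alternative for that reason.

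UMIs were summed over the kept cells of a library and divided by the library's total to give CPM. Depth limits precision: 3 UMIs, the floor used where a library had 0, equal 0.0625 CPM in strain L, 0.0655 in the May library and 0.0459 in the Nov library. Among named genes of at least 20 CPM the widest 95% counting interval reached 6.26%, 6.37% and 5.44% to either side. With 1 library per group there is no test, p-value or standard error. Ratios carry exact intervals for counts, shares carry exact Clopper-Pearson intervals, and both cover counting error only.

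Genes with a mean of at least 20 CPM over the libraries compared were counted as apart at 2-fold. The named genes were set by a rule before the data were examined: the 12 largest ratios each way in each comparison, the 3 members of each fixed list with the largest ratio, and 10 reference genes. The text gives the larger part of them. The 29 gene lists were fixed at the same time. A list with at least 5 members compared got a percentile of its median among 10000 random lists of the same size, drawn from 20 bins of mean expression. Arms with at least 20 genes were treated alike. Windows of about 30 neighbouring genes, the share of an arm per cell and the counts of cells very rich in interferon transcripts were added after the data had been seen.

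For cell phase and dissimilarity, each cell was thinned to 4475 UMIs, the 10th percentile of the shallowest library. Clusters, the share of an arm per cell and the counts of cells very rich in interferon transcripts used cells that were not thinned. Cell phase was scored with the lists of S phase and of G2 and mitosis. Dissimilarity was the mean over 20000 random pairs of cells, on log-normalized values of genes found in at least 5% of thinned cells. Clusters were made with the Leiden method on 2000 variable genes, 30 principal components and 15 neighbours, at a resolution of 0.5, and named only from fixed markers.

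The steps were tested on simulated data with known answers. For ratios and lists, these were drawn with counting error alone from the profile of the library named second in each comparison. For the May library over strain L, with 4206 simulated genes compared, all genes set 3-fold, 4-fold or 8-fold apart were recovered (100% each), 0% of those set 1.5-fold apart passed 2-fold, and 0 of 4001 unchanged genes did. The Nov library over strain L (4265 genes, 0 of 4062 unchanged genes) and over the May library (4291 genes, 0 of 4089) gave the same shares. At these depths counting error hardly moves a gene of at least 20 CPM, so these shares were nearly fixed in advance. They check the computation and say nothing on variation between cells or libraries. Of 100 simulated lists with no shift, 6, 5 and 4 lay outside the central 95% in the 3 comparisons.

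The alternatives tried were the scaling factors of edgeR 4.0.16 and DESeq2 1.42.0, CPM without mitochondrial and ribosomal protein genes, other CPM minimums, 5 CPM added before the ratio, means of per-cell CPM, all deposited cells, stricter filters, cells scored G1, a 1.5-fold limit, and other settings of thinning, clustering and dissimilarity. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9 was used, and R 4.3.3 for the scaling factors.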

Results

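Expression was measured in single cells of MCF7, an established human breast cancer line that is luminal and carries the estrogen receptor. Per the labels, 1 library came from the strain called L and 2 came from clone 9, which had been grown from that strain after limiting-dilution cloning. The clone 9 libraries carry the words May and Nov, and they are called the May library and the Nov library here. Each of the 3 groups held 1 library, so there was no replicate of any group, and every interval given covers counting error only. Droplet 3' libraries were made, and transcripts were counted as unique molecular identifiers (UMIs). After filtering, 3479 cells of strain L held 47976633 UMIs, 4144 cells of the May library held 45820961, and 4023 cells of the Nov library held 65340595. The median cell held 12812 UMIs and 2871 genes in strain L, 10029 UMIs and 2459 genes in the May library, and 15358 UMIs and 3225 genes in the Nov library. Levels are given as CPM, the UMIs of a gene with the total of each library scaled to the same sum, and positions are on GRCh38.

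All 3 libraries had the expression of luminal breast cells. KRT8 and KRT18, keratins of luminal epithelium, stood at 2948 and 3935 CPM in strain L, 2737 and 3334 CPM in the May library, and 2804 and 3911 CPM in the Nov library. ESR1, which encodes the estrogen receptor, stood at 87.2, 109 and 106 CPM in strain L, the May library and the Nov library. The proliferation marker MKI67 stood at 67.1, 67.9 and 77.3 CPM in that order, and the tumour suppressor PTEN at 42.2, 42.8 and 45.5 CPM. CDKN2A, which encodes the cell cycle inhibitor p16, had 3, 5 and 2 UMIs in whole libraries, at or near the floor of 3 UMIs, so no fold is given for it. The luminal list, with 20 of its members compared, had a median log2 ratio of 0.02 for the May library over strain L, inside its random range of -0.14 to 0.13. Markers of other cell types were low in every library. The 8 leukocyte markers in the table summed to 8.25, 13.1 and 12.9 CPM, the 6 endothelial markers to 3.27, 4.19 and 3.61 CPM, and the 10 mesenchymal markers to 30.9, 28.1 and 21.4 CPM. The 13 basal markers summed to 55.3, 81.0 and 27.8 CPM, of which CAV1 alone gave 11.2, 41.5 and 5.86 CPM.

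The comparison of the May library with strain L asked how expression in a clone differed from that of the strain it was derived from. Of 30 genes on the interferon list, the 6 that passed the minimum of 20 CPM were all higher in the May library. BST2, which tethers virus particles to the cell surface, stood at 88.4 CPM against 11.1 in strain L, 7.99-fold higher (95% counting interval 7.29 to 8.76). IFI6 stood at 111 against 19.8 CPM and the ubiquitin-like modifier ISG15 at 255 against 59.3 CPM, which are log2 ratios of 2.49 and 2.1. The serine protease gene KLK11 had the largest ratio of the genes compared that were higher, at 84.4 against 3.98 CPM or 21.2-fold (18.3 to 24.6). XIST, the long noncoding RNA of X chromosome inactivation, had the largest ratio the other way, at 1.68 CPM in the May library against 136 in strain L, 80.8-fold lower (64.5 to 102).

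In that comparison 4350 genes had a mean of at least 20 CPM, and 43 of them were at least 2-fold apart, 29 higher and 14 lower in the May library. Among those higher, PKP3, a plakophilin of desmosomes, stood at 39.1 against 3.59 CPM (log2 ratio 3.45), and NPY1R, a neuropeptide Y receptor, at 105 against 25.1 CPM (2.07). CAV1, the main protein of caveolae, had a log2 ratio of 1.90, the calcium-binding S100A6 of 1.82, the insulin-like growth factor binding protein IGFBP5 of 1.68 and the galectin LGALS1 of 1.57. SUSD3 and the mitochondrial carrier SFXN2 had log2 ratios of 1.90 and 1.68. Among those lower, S100A9 and S100A8, which together form calprotectin, stood at 6.90 against 54.2 CPM and at 9.32 against 47.1 CPM, which are log2 ratios of -2.97 and -2.34. Few cells carried many of these UMIs: the highest cell of the May library held 58.5% of its S100A9 UMIs and 48.0% of its S100A8 UMIs, and the highest cell of strain L held 18.5% and 16%. ZFPM1, a cofactor of GATA factors, had a log2 ratio of -2.29, the noncoding LINC00052 of -1.80 and the proteasome subunit PSMA7 of -1.08. ISG20, an interferon-stimulated exonuclease gene outside the interferon list, was lower as well (log2 ratio -1.51). With 5 CPM added before the ratio, which shrinks ratios over low levels, the log2 ratio was 3.31 for KLK11, 2.36 for PKP3, -4.40 for XIST and -2.31 for S100A9. Without the 10 highest cells of each gene it was -4.09 for S100A9, -3.73 for S100A8 and -7.25 for XIST.

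Of 22 fixed gene lists with enough members, 5 had a median outside the central 95% of 10000 random lists matched on expression, which describes these libraries only. All 6 interferon genes compared were at least 1.5-fold higher in the May library, with a median log2 ratio of 1.59 against a random range of -0.23 to 0.24. Among 9 immediate early genes, 3 were at least 1.5-fold higher and none lower, with a median of 0.52. KLF6 had a log2 ratio of 1.28 in this list, EGR1 of 0.99 and JUN of 0.74. Among 26 estrogen receptor targets, 5 were at least 1.5-fold higher and 2 lower, with a median of 0.21. The chemokine CXCL12 stood at 62.5 against 20.8 CPM, and PDZK1 and IGFBP4 had log2 ratios of 1.04 and 0.79, all higher in the May library. Genes of MHC class I presentation had a median of -0.36 over 7 members, with B2M, the light chain of class I molecules, at 125 against 223 CPM. The median of 9 p53 targets was -0.26, with GDF15 at 17.5 against 34.6 CPM and BBC3 the other way at 34.7 against 22.4 CPM. The p53 median lay inside the random range without the cells of the cluster led by LCN2 and S100A8 (-0.17), in cells scored G1 (-0.19), in cells thinned to equal depth (-0.15), without the 10 highest cells of each gene (-0.15) and with a minimum of 5 CPM (-0.01). The class I median did so in thinned cells (-0.19). The highest cell of strain L held 21.7% of that library's GDF15 UMIs.

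Positions in the annotation were 51022216 to 51028039 on chromosome 19 for KLK11, 17402939 to 17405648 on chromosome 19 for BST2, 27666061 to 27672218 on chromosome 1 for IFI6 and 1001138 to 1014540 on chromosome 1 for ISG15. PKP3 lies at 392614 to 404908 on chromosome 11, XIST at 73820651 to 73852723 on chromosome X and PSMA7 at 62136735 to 62143440 on chromosome 20. The 3' UMIs count the gene as a whole and carry no exon-level information.

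**Figure D1:**
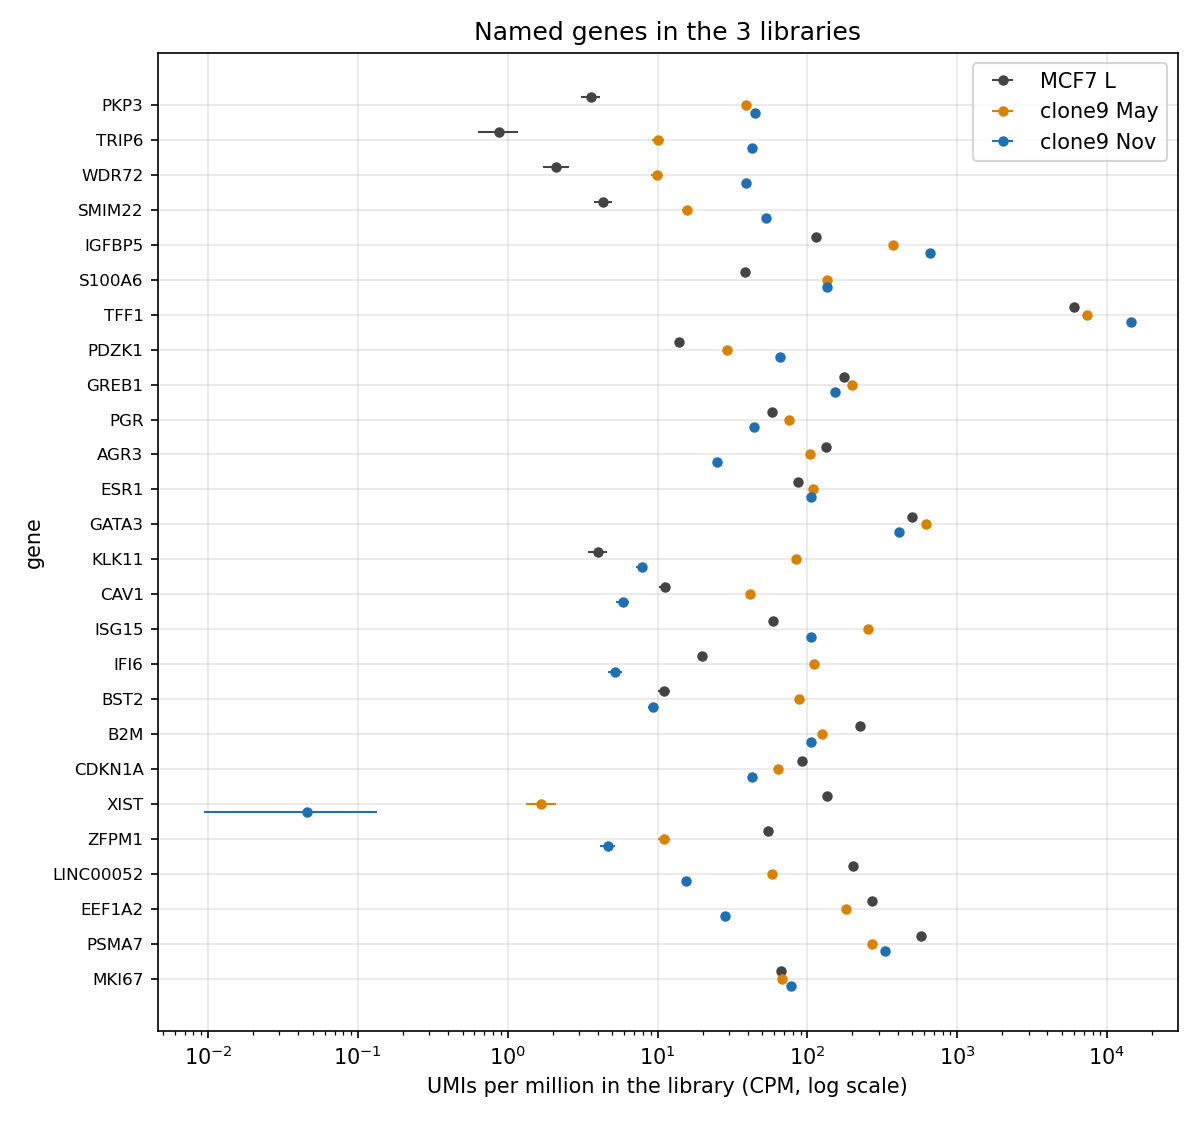
Levels of named genes in CPM on a log axis, with 1 point per gene for strain L (grey), the May library (orange) and the Nov library (blue) and 95% counting intervals as bars. KLK11 stands at 3.98, 84.4 and 7.85 CPM in that order, TRIP6 at 0.875, 10.1 and 42.9 CPM, and XIST at 136, 1.68 and 0.0459 CPM.

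The comparison of the Nov library with strain L asked the same question of the other library of the clone. It uses the same strain L library as the comparison before, so chance values of that library enter both. TRIP6, a LIM-domain protein of adhesion sites, stood at 42.9 CPM in the Nov library against 0.875 in strain L, 49.0-fold higher (36.1 to 68.1). The secreted trefoil peptide TFF1, an estrogen receptor target, stood at 14457 against 5997 CPM, 2.41-fold higher (2.40 to 2.42). XIST had 3 UMIs in the Nov library against 6513 in strain L, a ratio of 2957 with a counting interval of 1011 to 14341. EEF1A2, a translation elongation factor, stood at 28.0 against 269 CPM (log2 ratio -3.26), and LINC00052 at 15.4 against 203 CPM (-3.72).

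Of 4348 genes compared, 98 were at least 2-fold apart, 37 higher and 61 lower in the Nov library. With no CPM minimum the balance turned, with 1196 higher and 899 lower. Higher genes included WDR72 at 38.8 against 2.11 CPM (log2 ratio 4.20), PKP3 at 44.9 against 3.59 CPM (3.65) and SMIM22 at 53.2 against 4.36 CPM (3.61). IGFBP5 stood at 657 against 115 CPM, and the transcription factor genes NFATC4 and PITX1 had log2 ratios of 2.40 and 1.57. S100A6 and SUSD3 had log2 ratios of 1.83 and 1.88. The tubulin gene TUBA3D had a log2 ratio of 3.07. It has near-identical relatives, so its counts are uncertain. EEF1A2 also has a related gene, and whether reads were shared with it was not tested. Lower genes included ZFPM1 (log2 ratio -3.54), the planar polarity gene PRICKLE2 (-2.45), the small GTPase gene RAB31 (-2.41), AGR3 (-2.41), the protease gene PRSS23 (-2.25), the orphan nuclear receptor gene NR2F2 (-1.93) and the galectin gene LGALS3 (-1.91). S100A9 and S100A8 had log2 ratios of -1.53 and -1.40, and the highest cell of the Nov library held 22.2% and 25.8% of their UMIs. S100A8 was under 2-fold apart in cells scored G1 (-0.95) and stood at -2.01 without the cluster led by LCN2 and S100A8, and S100A9 stood at -2.15 under stricter cell filters. With 5 CPM added the log2 ratio of TRIP6 was 3.03, of WDR72 2.62, of SMIM22 2.64, of PKP3 2.54, of TUBA3D 2.19, of ZFPM1 -2.62 and of XIST -4.80, against -12.81 under stricter cell filters.

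List medians lay outside their random range for 11 of 21 lists. Among 18 genes of DNA replication, 16 lay above 0, with a median log2 ratio of 0.26, and RRM2 and GINS2 had ratios of 0.83 and 0.79. Of 30 genes of G2 and mitosis, 24 lay above 0 (median 0.22), with the kinetochore gene CENPF at 1.02. MYC targets and ribosome biogenesis genes had 17 of 19 members above 0 (median 0.26), with the spermidine synthase gene SRM at 0.70 and NPM1 at 0.56. The list of drug efflux, detoxification and drug target genes had a median of 0.30 over 8 members, with the quinone reductase gene NQO1 at 0.68. Lower medians were those of p53 targets (-0.48), class I presentation (-0.45), transcripts of the mitochondrial genome (-0.29), immediate early genes (-0.27), estrogen receptor targets (-0.18), adhesion and matrix genes (-0.18) and breast cancer drivers (-0.15). CDKN1A, the p53 target that encodes p21, stood at 42.5 against 92.6 CPM, B2M at 106 against 223 CPM and HLA-C, whose reads can be shared with other class I genes, had a log2 ratio of -1.07. MT-CO1 stood at 13578 against 21933 CPM, and the median mitochondrial share per cell was 6.45% in the Nov library and 8.91% in strain L. Estrogen receptor targets went both ways, with 7 of 26 at least 1.5-fold higher and 7 at least 1.5-fold lower. PDZK1 had a log2 ratio of 2.24, while AGR3 and PRSS23 were among the lower genes above. The 4 interferon genes compared had a median of -0.08, too few for a random range. ISG15 among them stood at 106 against 59.3 CPM, a log2 ratio of 0.84, but of 1.67 in cells scored G1 and of -0.13 without its 10 highest cells. In cells scored G1 alone, the medians of G2 and mitosis genes (0.16), MYC targets (0.18), drug-related genes (0.13), p53 targets (-0.20), class I presentation (-0.25) and immediate early genes (-0.12) lay inside their random ranges. Cells are scored G1 for low values of the lists of S phase and of G2 and mitosis. The change in the G2 and mitosis median, with 13 members compared in place of 30, is thus partly built in. With a minimum of 5 CPM the immediate early median was 0.03 and that of drug-related genes 0.13, and in thinned cells the medians of MYC targets (0.22) and drug-related genes (0.29) lay inside their ranges, as did that of MYC targets (0.22) from means of per-cell CPM.

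TRIP6 lies at 100867138 to 100873454 on chromosome 7, WDR72 at 53513741 to 53762878 on chromosome 15, SMIM22 at 4788397 to 4796491 on chromosome 16, IGFBP5 at 216672105 to 216695525 on chromosome 2 and EEF1A2 at 63488012 to 63499322 on chromosome 20.

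The Nov library was compared with the May library to describe how far libraries of the same clone were apart. Interferon genes were lower in the Nov library: IFI6 stood at 5.17 against 111 CPM, 21.5-fold lower (19.3 to 24.1), and BST2 at 9.31 against 88.4 CPM, 9.50-fold lower (8.72 to 10.4). KLK11 stood at 7.85 against 84.4 CPM (log2 ratio -3.43) and RAMP3, which modifies the calcitonin receptor, at 3.37 against 40.5 CPM (-3.59). TRIP6 and WDR72 were higher in the Nov library, at 42.9 against 10.1 CPM and 38.8 against 9.89 CPM. TFF1 stood at 14457 against 7323 CPM, a log2 ratio of 0.98.

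Of 4368 genes compared, 68 were at least 2-fold apart, 13 higher and 55 lower in the Nov library. CAV1 (log2 ratio -2.82), EEF1A2 (-2.70), RAB31 (-2.61), PRICKLE2 (-2.35), the adenylate cyclase gene ADCY1 (-2.14), AGR3 (-2.06) and LINC00052 (-1.92) were lower. GATA3-AS1 had a log2 ratio of -1.84. It is antisense to GATA3, a luminal transcription factor gene that stood at 409 against 621 CPM, and the strand setting of the counting was not given in the sources used here. The neuropeptide gene GAL stood at 59.6 against 19.7 CPM, and SMIM22 (1.76), TUBA3D (1.97), NFATC4 (1.35), GPR160 (1.29), PITX1 (1.2), PDZK1 (1.19) and the spindle gene TROAP (1.06, and 0.97 with 5 CPM added) were higher. With 5 CPM added the log2 ratio of IFI6 was -3.52, of KLK11 -2.80, of RAMP3 -2.44 and of CAV1 -2.10. The progesterone receptor gene PGR stood at 44.1 against 75.5 CPM.

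Medians of 10 of 22 lists lay outside their random range. All 6 interferon genes compared were at least 1.5-fold lower in the Nov library (median log2 ratio -1.25). ISG15, at 106 against 255 CPM, depended on rare cells in the Nov library. There 3 of 4023 cells held 53.8% of its UMIs, and 1 of them alone held 51.3%. The ISG15 level in the Nov library was 49.0 CPM without these 3 cells. The median mitochondrial share of these 3 cells was 0.19%, against 6.45% in the library. Its log2 ratio was -1.27, but -0.48 in cells scored G1 and -2.27 without its 10 highest cells. None of 10 immediate early genes lay above 0, and 6 were at least 1.5-fold lower (median -0.67), with KLF6 at -1.80, FOS at -1.13 and JUN at -1.01. Adhesion and matrix genes had a median of -0.39, with LGALS3 at -1.74 and LGALS1 at -1.29. Of 26 estrogen receptor targets, 7 were at least 1.5-fold lower and 2 higher (median -0.34). Class I presentation (-0.32) and breast cancer drivers (-0.23) were lower as well. Higher medians were those of fatty acid synthesis (0.39), MYC targets (0.29), nuclear-encoded oxidative phosphorylation (0.25) and G2 and mitosis genes (0.22). Of the 32 oxidative phosphorylation genes, 28 lay above 0, among them ATP5G3 at 0.53 and UQCRQ at 0.51. The fatty acid carrier gene FABP5 had a log2 ratio of 0.82 and the desaturase gene SCD of 0.49. The median of MYC targets lay inside its random range in cells scored G1 (0.16).

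**Figure D2:**
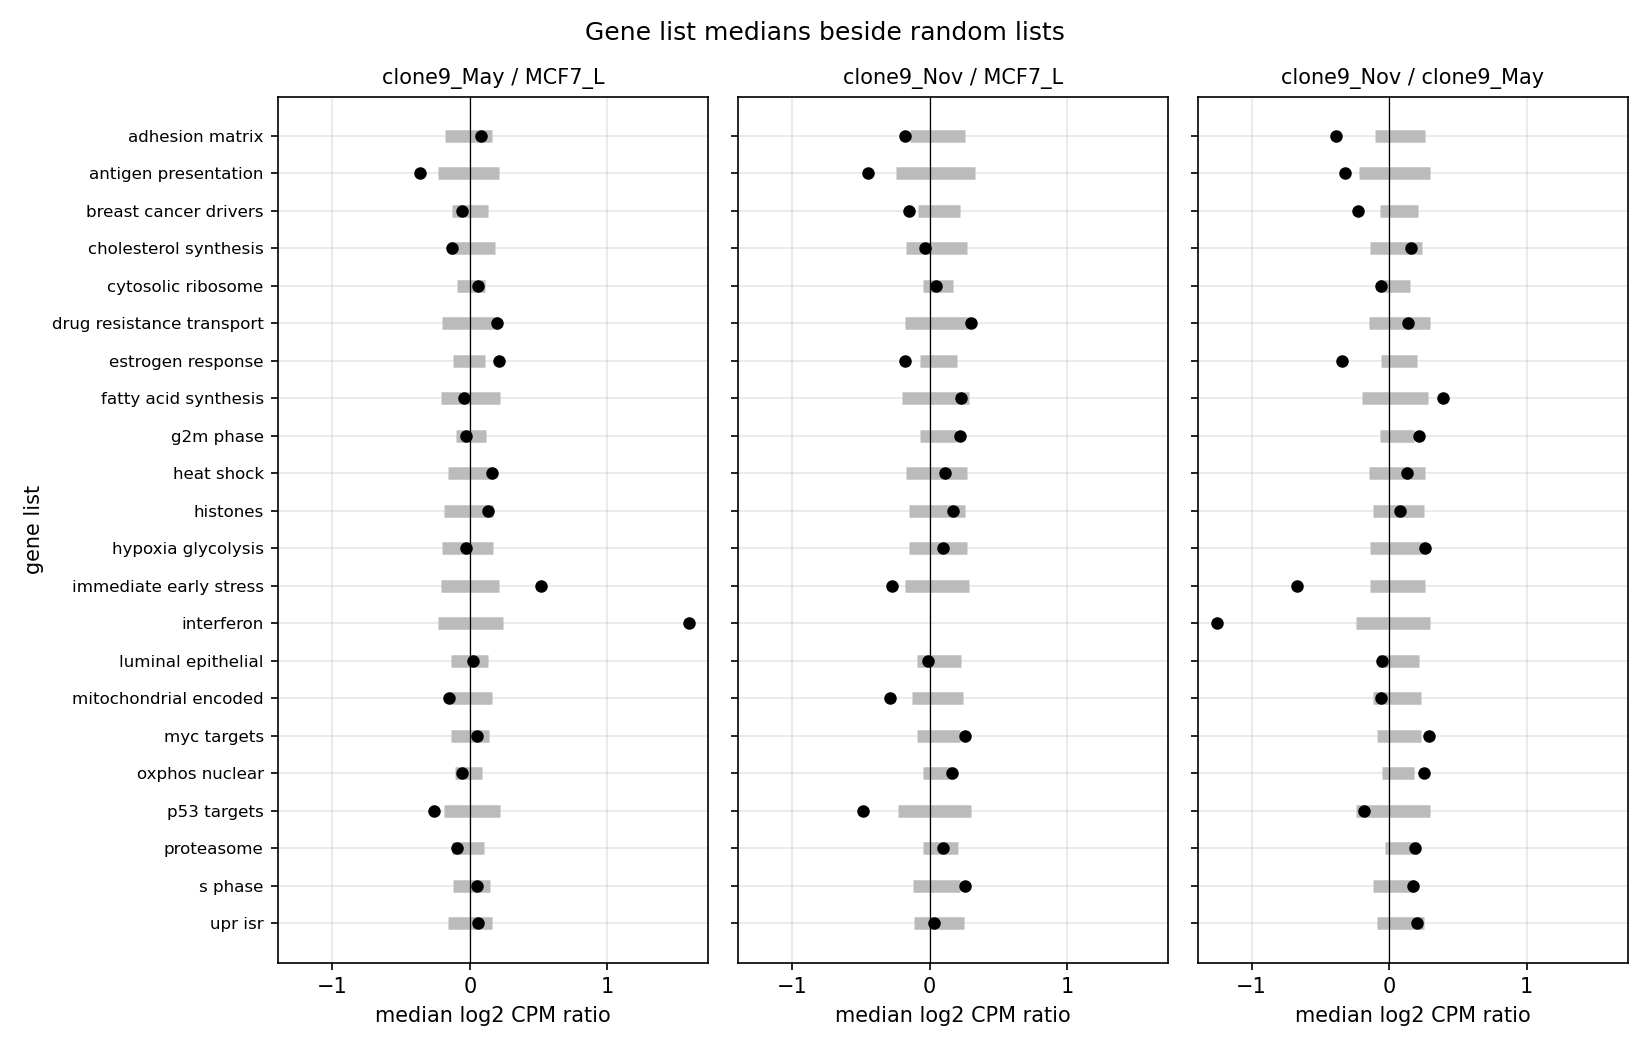
Median log2 CPM ratio of each fixed gene list in the 3 comparisons, drawn as points over bars that span the central 95% of 10000 random lists matched on expression. The interferon median lies at 1.59 for the May library over strain L and at -1.25 for the Nov library over the May library.

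Chromosome arms with at least 20 genes compared were treated as further lists, 41 in all. For the May library over strain L, 16 arms had medians outside their random range. The median log2 ratio was 0.32 on 13q, 0.26 on 16p and 0.21 on 22q, and -0.27 on 12p, -0.23 on 9q, -0.21 on 15q and -0.20 on 6q. For the Nov library over strain L, 23 arms lay outside, with -0.37 on 9q, -0.32 on 3p, -0.29 on 10p and -0.25 on 15q, and with 0.22 on 16p, 0.22 on 4q, 0.21 on 12p and 0.20 on 16q. On 9q, 14 of 149 genes lay above 0. For the Nov library over the May library, 18 arms lay outside. Genes of 12p had a median of 0.55, with 35 of 37 above 0, genes of 3q had 0.28, with 101 of 114 above 0, and genes of 3p had -0.40, with 7 of 100 above 0. The arms Xp and Xq had medians of 0.02 and 0.03 for the May library and 0.11 and 0.05 for the Nov library over strain L, inside their random ranges, while XIST lay far below strain L.

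The share of 3p among the UMIs of 3p and 3q genes was also taken in each cell. It used 94 genes of 3p and 107 of 3q with a mean of at least 20 CPM, without ribosomal protein genes. Its median was 51.9% in strain L, 54.1% in the May library and 44.6% in the Nov library. The variance over cells was 2.22, 2 and 3.42 times that of binomial counting in the same order, so the spread exceeded counting error in every library. This ratio grows with the UMIs counted per cell, whose medians were 199, 154 and 238. It is therefore not compared between libraries. A midpoint of 49.3% was set between the medians of the clone 9 libraries, so some separation of these libraries is built in. On its May side lay 80.6% of the May cells, 20.7% of the Nov cells and 69.1% of strain L cells. The same split for the share of 12p among 12p and 12q was weaker, with 70.5%, 29.5% and 59.5% in that order.

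**Figure D3:**
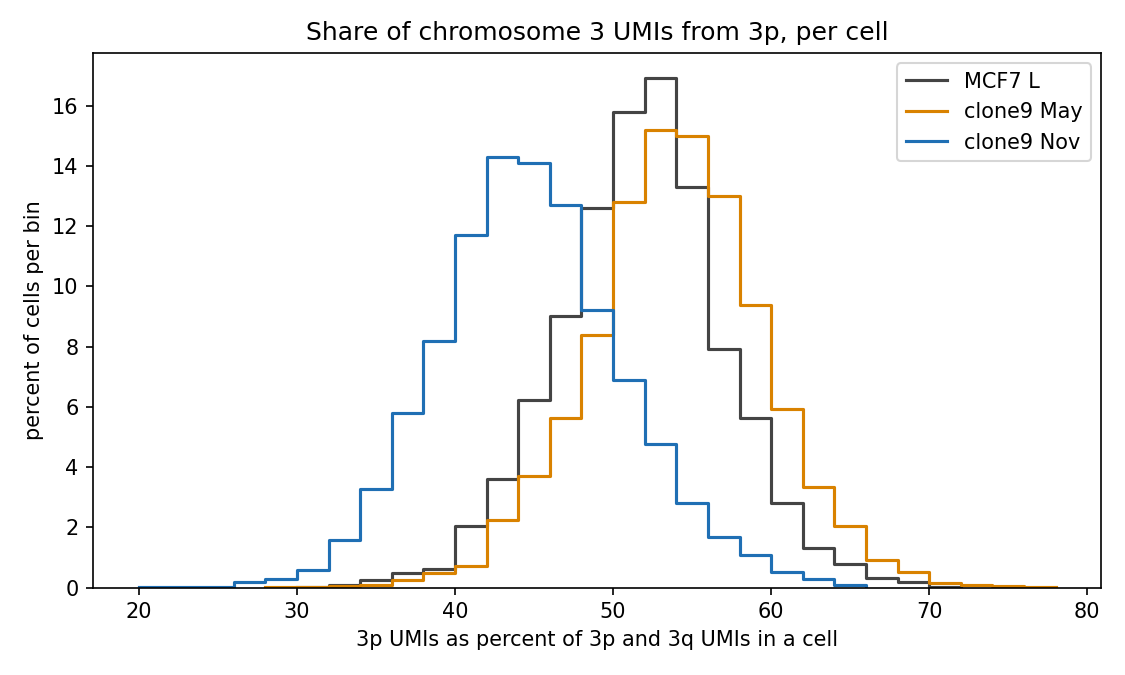
Distribution over cells of the share of 3p among UMIs of 3p and 3q genes, in percent, with 1 line per library. The median lies at 51.9% in strain L, 54.1% in the May library and 44.6% in the Nov library, and the lines overlap.

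Windows of about 30 neighbouring genes showed differences within arms, in a division made after the arms had been seen. At 56.5 to 64.1 Mb of chromosome 20, which holds PSMA7, LSM14B and EEF1A2, the median log2 ratio over strain L was -0.43 in the May library and -0.36 in the Nov library, with 30 and 31 of 34 genes below 0. At 193.1 to 217.6 Mb of chromosome 1 it was 0.16 and 0.49. The shift of 22q in the May library over strain L did not span the arm. Its median was -0.05 at 17.1 to 36.4 Mb, with 24 of 43 genes below 0. At 36.5 to 50.3 Mb it was 0.41, with 2 of 42 below 0. On chromosome 3, all 30 genes of the window at 37.1 to 49.0 Mb lay below 0 in the Nov library against the May library (median -0.49).

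**Figure D4:**
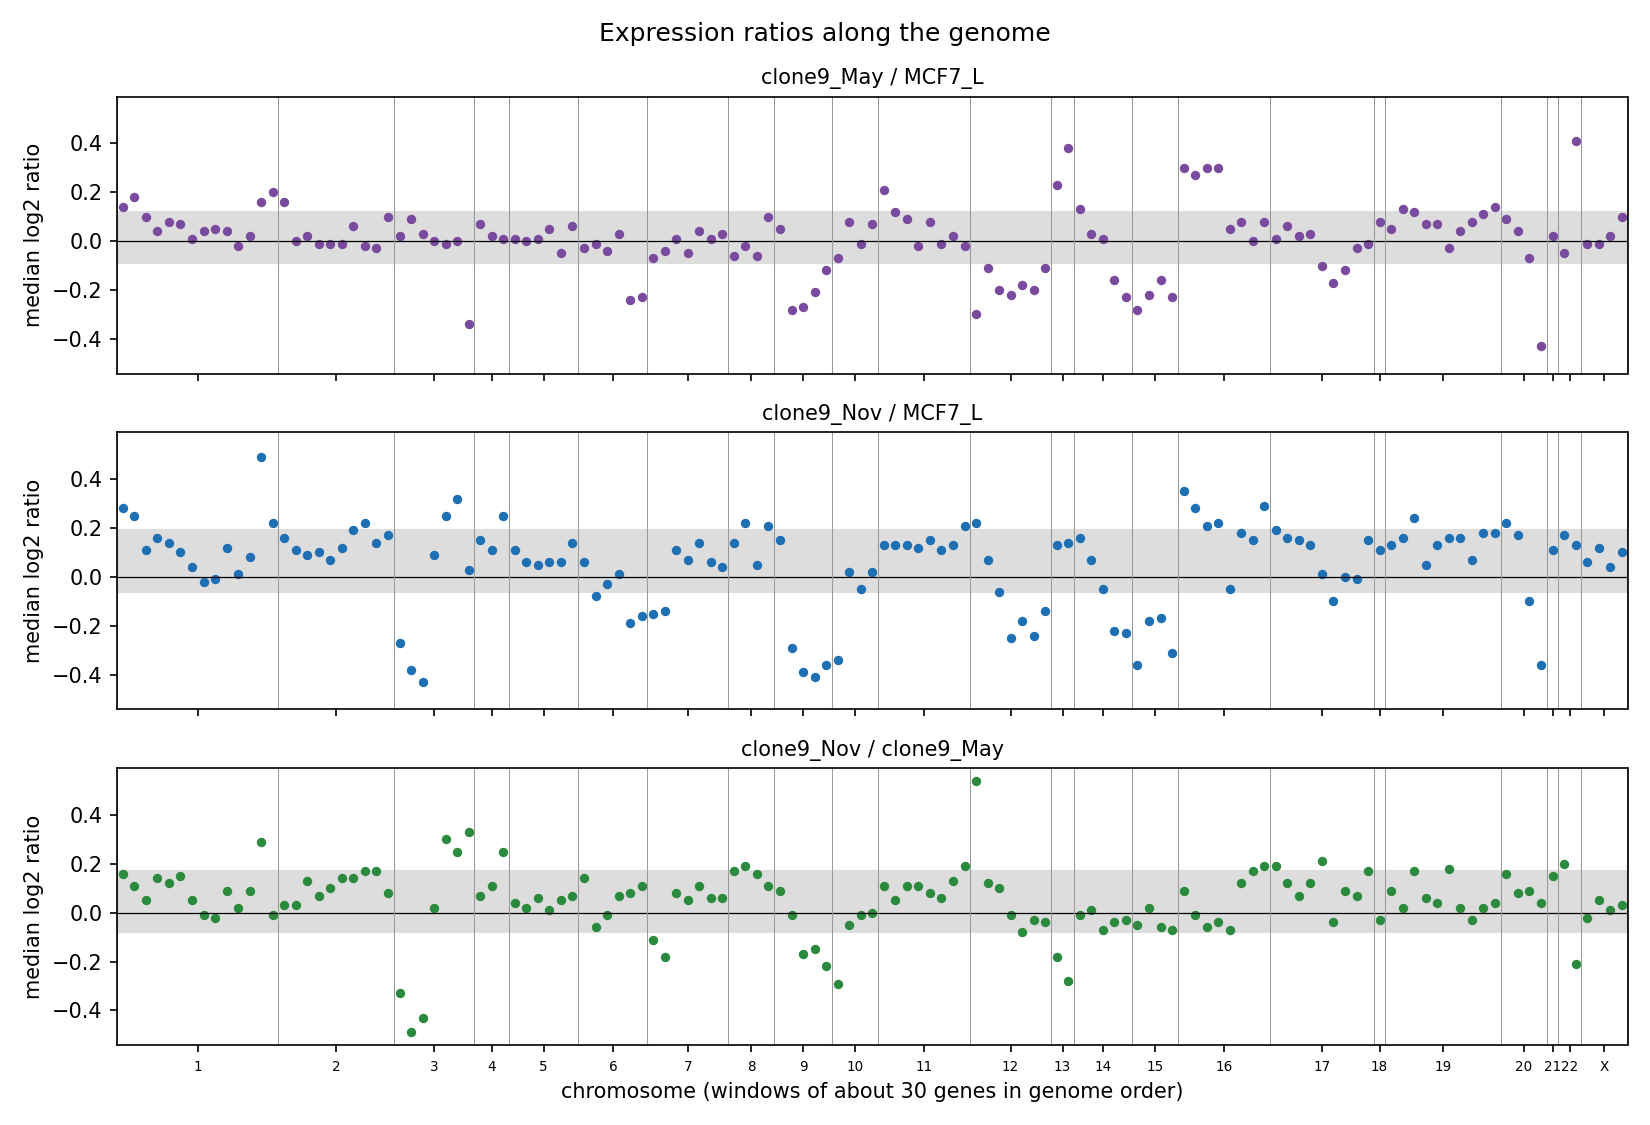
Median log2 CPM ratio of windows of about 30 neighbouring genes in genome order, drawn as points in the 3 comparisons over a grey band that spans the central 95% of medians of 10000 random sets of 30 genes. The window at 0.8 to 27.1 Mb of chromosome 12 lies at -0.30 for the May library over strain L and at 0.54 for the Nov library over the May library.

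Cells scored for S phase genes made up 36.0% of strain L (exact 95% interval 34.4 to 37.6), 33.5% of the May library (32.0 to 35.1) and 41.7% of the Nov library (40.2 to 43.2), with every cell thinned to 4475 UMIs. For G2 and mitosis genes the shares were 19.8% (18.4 to 21.2), 17.7% (16.5 to 19) and 23% (21.7 to 24.3). Without thinning the S shares were 35.7%, 34.6% and 43.7%, and the G2 and mitosis shares were 19.1%, 16.5% and 21.5%. When scores above 0.1 were required, the order of strain L and the May library turned for S phase, at 11.9% (10.8 to 13) and 13.4% (12.3 to 14.5). Thinning left out 107 cells of strain L, 414 of the May library and 42 of the Nov library as too shallow. The scores are ranges and not types: 36.2%, 33.2% and 33.8% of cells lay within 0.05 of the limit. Free RNA was not measured, so no rate of division is read from these calls.

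Cells of clone 9 were compared with one another, beside cells of strain L, to describe how varied a population grown from a single cell was. The mean dissimilarity of random pairs of cells (1 minus Pearson's r over genes) was 0.4201 in strain L, 0.4206 in the May library and 0.4204 in the Nov library, with all cells at equal depth. Cells simulated from the mean profile of each library, with sampling alone, gave 0.3952, 0.3969 and 0.3960, so the excess was 0.0250, 0.0237 and 0.0245. On the 2000 most variable genes the excess was 0.0357, 0.0392 and 0.0361, so the order of the libraries depended on the genes used. The measure is coarse: a simulated equal mix of the strain L and Nov profiles had an excess of 0.0028, and 1 simulated profile 0.0004, on 4359 genes in place of the 6314 used for the libraries. Without thinning the excess was 0.0453, 0.0374 and 0.0440, while the ratio of the dissimilarity itself to strain L was 1.107 for the May library, the shallowest, and 0.9323 for the Nov library.

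Clustering of all cells gave 9 clusters, of which 3 took at least 80% of their cells from 1 library and together held 55.6% of the cells. Such clusters, led by XIST and ZFPM1 for strain L, by KLK11 and BST2 for the May library and by SMIM22 and IGFBP5 for the Nov library, may be the libraries and not types of cell. The cluster led by XIST held 41 cells of the May library and 3 of the Nov library. Whether the XIST UMIs of these libraries lay in those cells was not tested. The largest cluster, with 2819 cells, was shared: it held 23.6% of strain L, 22.1% of the May library and 26.9% of the Nov library. Its median cell held 6501 UMIs, against 12812, 10029 and 15358 in the whole libraries. Whether depth sets it apart was not tested. Another 2 clusters were G2/M-like, one led by CCNB1 and CDC20 with 8 fixed markers among its top genes and the other by PIF1 and CENPA with 6. The first held 7.53% of strain L, 6.01% of the May library and 6.61% of the Nov library, and the second 0.172%, 6.47% and 9.45%, although CENPA stood at 48.1, 45.0 and 52.9 CPM in the whole libraries. No cluster could be named for basal, mesenchymal, leukocyte or endothelial cells.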

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

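Thinned counts, the 5% of cells with most UMIs, the cluster led by LCN2 and S100A8, the 10 highest cells of each gene and the GC trend were chosen as alternatives after the data had been seen; the others were set before. Of the named genes at least 2-fold apart, 23 of 27 (May library over strain L), 29 of 35 (Nov library over strain L) and 28 of 32 (Nov over May) stayed so in every setting run on single genes. Counts of genes apart, in the same order, were 43, 98 and 68. They were 74, 165 and 119 without mitochondrial and ribosomal protein genes, 141, 289 and 201 with a minimum of 5 CPM, 10, 21 and 15 with 100 CPM, 1532, 2095 and 1708 with no CPM minimum, and 213, 397 and 302 at 1.5-fold. By construction these settings compare more or fewer genes, let in genes with few UMIs, or lower the limit. Genes higher in the Nov library made up 19.1% of those apart from the May library, and 0 of 15 with 100 CPM. That share was 30.8% with 5 CPM, 42.6% with no minimum and 43% at 1.5-fold. Of genes apart from strain L, those higher in the Nov library made up 37.8%. There the share was 46% with 5 CPM, 57.1% with no minimum and 45.3% at 1.5-fold. Lists outside their random range stayed outside in every setting for 3 of 5, 5 of 11 and 9 of 10 lists. For the Nov library over strain L, the G2 and mitosis list lay inside only in cells scored G1, which are picked partly by that list. The immediate early median of the Nov library over strain L reversed to 0.03 with 5 CPM, where 17 members were compared in place of 9; the cause was not tested.

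Requiring scores above 0.1 gave S shares of 11.9%, 13.4% and 17.6% and G2 and mitosis shares of 13%, 12.7% and 16% in strain L, the May and the Nov library, by construction of a stricter limit; the S order of strain L and the May library turned (cause not tested). Unthinned, the Nov shares were 43.7% and 21.5%. Dissimilarity relative to strain L was 1.001 in both clone 9 libraries, against 1.107 and 0.9323 unthinned, which carries depth by construction, and 1.008 and 0.9904 on the 2000 most variable genes (cause not tested). The excess over sampling, relative to strain L, was 0.948 and 0.98, against 0.826 and 0.971 unthinned and 1.1 and 1.01 on those genes. There were 5 clusters at resolution 0.25, of which 1 took at least 80% of its cells from 1 library and held 20.3% of the cells. At resolution 1.0 there were 17, of which 8 did so and held 59.2%. The alternatives planned for cells without a library were not run, since every cell had one. No paired analysis was possible because each group has 1 library. Depth limits genes under the 20 CPM minimum most, and a missing replicate limits every comparison.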

Other observations

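The windows, the very interferon-rich cells, the dependence of chromosome 3 and interferon values on the 10 highest cells, the genes matched on GC content, the leukocyte comparison and the comparison of interferon genes with the other library of the clone were chosen as tests after related results had been seen; the other tests were written before theirs. Some small clusters held cells of every library. A cluster of 307 cells was led by LCN2, a secreted lipocalin, S100A8, S100A9 and the stress cytokine GDF15. LCN2 itself had 363 UMIs in strain L, 14 in the May library and 18 in the Nov library, so the cells of the cluster differ between libraries and its shares are not compared. The chemokine gene CCL5 also ranked among its top genes, but 1 Nov cell held 256 of the 405 CCL5 UMIs of the Nov library, the May library had 66, of which 48 lay in its 13 interferon-rich cells, and strain L had 4. The cluster had 1 basal marker, KRT17, among its top 10 genes and stays unnamed, and its median mitochondrial share was 1.87%, against 8.91%, 7.54% and 6.45% in whole libraries. Another cluster of 564 cells was led by IL24, ASCL1, a neural transcription factor gene, and FAM134B. It held 0.891% of strain L, 6.9% of the May library and 6.14% of the Nov library. A cluster of 54 cells led by IFI27 and MAD2L1 had a median mitochondrial share of 0.0887%.

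Some interferon transcripts of the Nov library lay in very few cells. A limit of 8000 CPM over the interferon list, set after seeing the spread, was passed by 3 of 4023 cells there, by 13 of 4144 in the May library and by 3 of 3479 in strain L. The 3 Nov cells held 21.8% of the UMIs of the whole list, so most lay in other cells, and 3723 of 6922 ISG15 UMIs, 67 of the 68 UMIs of the interferon lambda gene IFNL1 and 392 of 405 UMIs of CCL5. For ISG15, 1 of these cells alone held 3549 UMIs. The median mitochondrial share was 0.19% in these 3 cells against 6.45% in the Nov library, 6.86% against 7.54% in the 13 May cells, and 5.18% against 8.91% in the 3 cells of strain L. The median cell, by contrast, had 215 CPM of the list in strain L, 597 in the May library and 192 in the Nov library.

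The lower expression of 3p and higher expression of 3q genes in the Nov library against the May library was weighed first. The 3p median was -0.40. Genes of other chromosomes matched to the 3p genes on transcript GC had a median of 0.04 (central 95% of draws -0.02 to 0.11). This argues against GC content as the whole cause. In cells thinned to equal depth the 3p median was -0.39, so the larger weight of deep cells in the sums did not carry it. Thinning leaves the expected proportions of genes within a cell unchanged, so it cannot decide on depth in other respects. Without the 10 highest cells of each gene, 93.5% of 3p genes lay below the median of all genes, which argues against a few cells or genes. A difference in dosage of the arms is a candidate explanation: it needs genes of low and of high level to be lowered alike, and the medians were -0.42 and -0.36 for the lower-expressed and higher-expressed genes. No DNA data were analysed here, and a difference between cultures or library preparations stays open.

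The higher interferon genes of the May library against strain L were weighed next. Their median of 1.59 was 1.61 without the 10 highest cells of each gene, which argues against rare cells. In thinned cells it was 1.55, so the larger weight of deep cells did not carry it. Thinning keeps the expected proportions within a cell, so it cannot decide on depth in other respects. Leukocyte markers summed to 13.1 CPM in the May library and 8.25 in strain L, yet stood at 12.9 CPM in the Nov library (May over Nov 1.02), where interferon genes were low, which argues against leukocytes. In the Nov library, of the same clone, the 6 interferon genes had a median log2 ratio of -0.12 over strain L, with IFI6 at 5.17 CPM and BST2 at 9.31 CPM but ISG15 higher at 106 against 59.3 CPM (log2 ratio 0.84, 1.67 in cells scored G1 and -0.13 without its 10 highest cells), which argues against a trait of the whole set present in both libraries of clone 9. Differences between the cultures or the library preparations stay open and were not tested.

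The lower S100A8 and S100A9 of the May library against strain L were weighed last, since few cells held many of their UMIs. Without the 10 highest cells of each gene the log2 ratios were -3.73 for S100A8 and -4.09 for S100A9, farther from 0 than with them. These cells held most of the UMIs: 1.16 and 0.873 CPM were left in the May library (53 and 40 UMIs) and 15.4 and 14.9 CPM in strain L. The difference was thus not carried by the 10 highest cells of each gene alone. Leaving out the same number of cells in each library cannot decide whether strain L had more such cells, so rare high cells stay open as a cause. Without the cluster led by LCN2 and S100A8 the log2 ratios were -2.61 and -3.06. The cluster held most of the UMIs of both genes. For S100A8, 63 of 427 UMIs were left in the May library and 399 of 2258 in strain L. For S100A9, 52 of 316 and 449 of 2600 were left. A ratio over so small a remainder cannot decide whether the cells of the cluster account for the difference. The remaining levels were 1.41 and 1.16 CPM in the May library against 8.63 and 9.72 in strain L, and free RNA from the cells of that cluster could still add to them, which was not tested.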
